A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

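The series measured messenger RNA in whole rice seedlings (Oryza sativa, Japonica group) by RNA sequencing. Per the labels, 12 libraries were made, 3 for each of 4 groups: wild type (WT) and the line raf-b2/3, each without mannitol and after 6 hours in 800 mM mannitol. The seedlings were 5 days old. The genotype label of raf-b2/3 calls it a knockdown of B2/3 RAF kinases, while the protocols call it a mutant, so it is named by its line name here. Reads were paired, 150 bases long, and came from a strand-specific library kit, per the labels' protocols.

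The authors deposited 1 table with 29358 loci. It holds FPKM values (fragments scaled to the length of the gene and to the mapped fragments of the library) for the 12 libraries, the authors' mean FPKM per group, and the authors' log2 fold changes and p-values for mannitol against control within each genotype. Whether those deposited p-values are raw or adjusted is not stated. The submitters' processing notes name Trimmomatic, DESeq2, edgeR and the genome build IRGSP-1.0, with no versions of the tools and no order of the steps. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes therefore may not have been told apart, and reads of near-identical paralogs such as RAB16A to RAB16D, the RBCS genes and small heat shock proteins could have been shared between copies. The FPKM columns summed to 579123 to 617852 per library.

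Because an FPKM value comes from a whole number of fragments, the low values of a locus are multiples of what 1 fragment is worth. With a tolerance of 0.01 of a fragment, whole fragments could be recovered for 29356 loci, and for 2 they could not. The recovered totals were 37117417 to 39024605 fragments per library (median 38095607), and the relative depths were 0.982 to 1.041. Tested on 3000 simulated genes, the recovery gave back the exact counts of 99.9% of them. Intervals and floors computed from recovered reads cover counting error only.

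The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with 1 mean per group over all 12 libraries and 1 shared estimate of the spread (12.1 degrees of freedom). Loci with FPKM of 1 or more in at least 3 libraries were tested, 22371 in all. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size, and for the genotype by mannitol interaction at the adjusted p alone. Counts of list members that rose or fell use the adjusted p alone. With 1 library left out, a call whose adjusted p rounded to 0.05 was not tallied as ended, while the counts of list members passing leave it out. A log2 change is on the log2(FPKM + 1) scale and understates the change of genes with low values. The interaction of such genes can be understated or overstated, because the added 1 shrinks the response more in the genotype with the lower levels. In simulated data, 50 genes were changed at each size, drawn from genes above a set mean level. Recovery was counted at the adjusted p alone with the right sign, without the fold threshold, so the shares do not describe the rule with that threshold. So counted, a log2 change of 1 was recovered for 96.0% of genes in the WT response, 94.0% in the raf-b2/3 response, 86.0% in the interaction, 90.0% in the genotype difference without mannitol and 90.0% in that under mannitol. At a log2 change of 0.5 the shares were 52.0%, 56.0%, 42.0%, 48.0% and 64.0%. Of the calls made at the adjusted p alone, 7.0%, 3.4%, 4.8%, 4.6% and 5.4% were false. Far fewer genes were changed in the simulation than passed the adjusted p in the real WT and raf-b2/3 responses (14151 and 13923). The simulated shares therefore need not hold for those responses.

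The response size was compared over genes that passed the threshold for the mean of both genotypes' responses, a choice that favours neither genotype, as the median ratio of the raf-b2/3 to the WT log2 response. Its test was limma's fry on the interaction. Fry tests whether the genes of a set move on balance in a common direction, and its mixed form whether they change in either direction. Neither compares the set with other genes.

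The table gives locus numbers of the LOC_Os type for 29330 loci and another type for 28, with no gene names. The gene names come from 198 entries that pair a name with a locus number. Of these, 92 were fixed before the data were examined and 106 were added once the type of locus number had been seen, before any test. The entries were checked against a reference gene table (assembly ASM3414082v1), which does not carry these locus numbers, by chromosome and by order along it. The check kept 184 entries. Of these, 130 matched in chromosome and order and 54 had no symbol in the reference, so the names of the latter rest on the entry alone. Among them are BZIP46, GOLS1, PRODH, PYL6, NAC10, RAB16A and the Raf-like kinases DSM1, EDR1, CTR1-like 1 and CTR1-like 2. No coordinates are given, because the builds differ. Of the names kept, 177 were tested.

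The names form 22 lists. The lists of LEA and dehydrin proteins, clade A PP2C phosphatases, abscisic acid (ABA) receptors, SnRK2 kinases, ABA metabolism, stress transcription factors, osmolyte synthesis, Raf-like kinases, aquaporins and single stress markers were fixed before the data were examined. The photosynthesis and root marker lists were fixed then and completed later. The lists of drought transcription factors, JAZ repressors, type-A response regulators, cell cycle genes, expansins, heat shock genes, antioxidant enzymes, alpha-amylases, seed storage proteins and osmolyte turnover were added. Root markers, photosynthesis genes, seed storage proteins and alpha-amylases stand for the tissues a seedling sample could hold. Lists with 5 or more tested members (18) were tested with limma's camera at a preset correlation of 0.01 between genes. Adjustment was over these lists and the 5 comparisons (90 tests). Camera with an estimated correlation and fry were run as alternatives. Of the 35 list results past the threshold with the preset correlation, 0 passed it with an estimated one, where adjusted p ran from 0.19 to 0.65.

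Genes were named by a rule written before the data were examined. For each comparison it takes the 6 highest and the 6 lowest log2 changes among named genes past the threshold that have a mean FPKM of at least 5 and, except for the interaction, no overlap between the libraries of the groups compared. Any list member may also be named with its value. Loci given by number alone are at most 2 in each direction per comparison, plus 1 group of neighbouring loci and 1 further locus chosen after their values were seen.

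The alternatives, fixed before the data were examined, were a pseudocount of 0.1, no filter and a filter at FPKM 5, 3 other scalings, array weights, a replicate block, the groups compared alone, the other fold threshold and leaving out each library in turn. Added after the data were seen were limma-voom on the recovered reads and a fit without WT control 2 and raf-b2/3 mannitol 3 together. Simulations, tables and figures used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. A count test was not used as the main test because the deposited values are FPKM. List entries for NRT2.1, GLUB1, GLUB2, GLUB4 and RAMY3A were not analysed here.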

Results

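Gene expression was profiled by RNA sequencing in whole 5-day-old rice seedlings of the wild type (WT) and of raf-b2/3, a line impaired in B2 and B3 RAF protein kinases. Seedlings were sampled without treatment or after 6 hours in 800 mM mannitol, a sugar alcohol that withdraws water from plant cells and so imposes osmotic stress. Each of the 4 groups had 3 libraries, and between 37117417 and 39024605 recovered fragments per library lay behind the FPKM values. Between 20531 and 21222 loci per library had an FPKM of 1 or more. The labels do not say whether the libraries of a group came from separately grown seedlings, so the p-values measure the spread between these libraries, which may be technical.

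Of the Raf-like kinases examined, DSM1 (LOC_Os02g50970), whose mutant is known to be sensitive to drought, was lower in raf-b2/3. Its FPKM in the WT libraries was 22.8, 19.9 and 22.4 without mannitol and 21.9, 21.7 and 22.7 with it. In raf-b2/3 it was 8.87, 9.54 and 8.91 without mannitol and 10.6, 9.26 and 10.6 with it. The log2 difference was -1.16 (SE 0.07) without mannitol and -1.06 under mannitol, with limma adjusted p of 3.4e-06 and 3.5e-06. The labels name no loci for the targeted kinases, so whether DSM1 or the other 3 members of this list are among the targets was not determined, and their levels do not check the labels. EDR1 (LOC_Os03g06410) stood at 24.3 ± 1.48 FPKM in WT and 29.0 ± 1.44 in raf-b2/3 without mannitol (SD, n = 3), and at 44.5 ± 1.03 and 54.8 ± 7.4 under mannitol. CTR1-like 2 (LOC_Os02g32610) stood at 8.5 ± 0.625 and 10.1 ± 1.46 without mannitol and at 28.6 ± 2.37 and 31.8 ± 1.67 under it. CTR1-like 1 (LOC_Os09g39320) stood at 6.3 ± 0.781, 6.42 ± 0.256, 5.84 ± 0.341 and 6.39 ± 0.557 in WT control, WT mannitol, raf-b2/3 control and raf-b2/3 mannitol. By library, EDR1 ranged from 22.6 to 25.5, 43.3 to 45.2, 27.9 to 30.7 and 46.5 to 60.7 in these 4 groups, CTR1-like 2 from 7.78 to 8.89, 25.9 to 30.3, 9.15 to 11.8 and 30.8 to 33.8, and CTR1-like 1 from 5.4 to 6.75, 6.14 to 6.65, 5.44 to 6.07 and 5.87 to 6.98. EDR1 and CTR1-like 2 rose under mannitol in both genotypes, by log2 0.85 and 1.64 in WT and 0.89 and 1.57 in raf-b2/3 (limma adjusted p of 4.4e-06, 4.6e-08, 4.0e-06 and 9.9e-08). Without mannitol, DSM1 alone differed between genotypes, and adjusted over the list alone 1 member was lower and 1, EDR1, was higher (log2 0.25, adjusted p 0.2 over all genes).

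Mannitol separated the libraries along the first principal component, which held 71.6% of the variance, and genotype separated them along the second, which held 12.3%. Within groups, Pearson's r across genes was 0.981 to 0.991 for WT control, 0.992 to 0.993 for WT mannitol, 0.988 to 0.989 for raf-b2/3 control and 0.984 to 0.989 for raf-b2/3 mannitol. The library raf-b2/3 mannitol 3 lay closer to WT mannitol (r 0.974 to 0.981) than raf-b2/3 mannitol 1 (0.963 to 0.970) and 2 (0.964 to 0.971). WT control 2 stood apart on the third component (score 33.67), which held 4.5%.

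**Figure D1:**
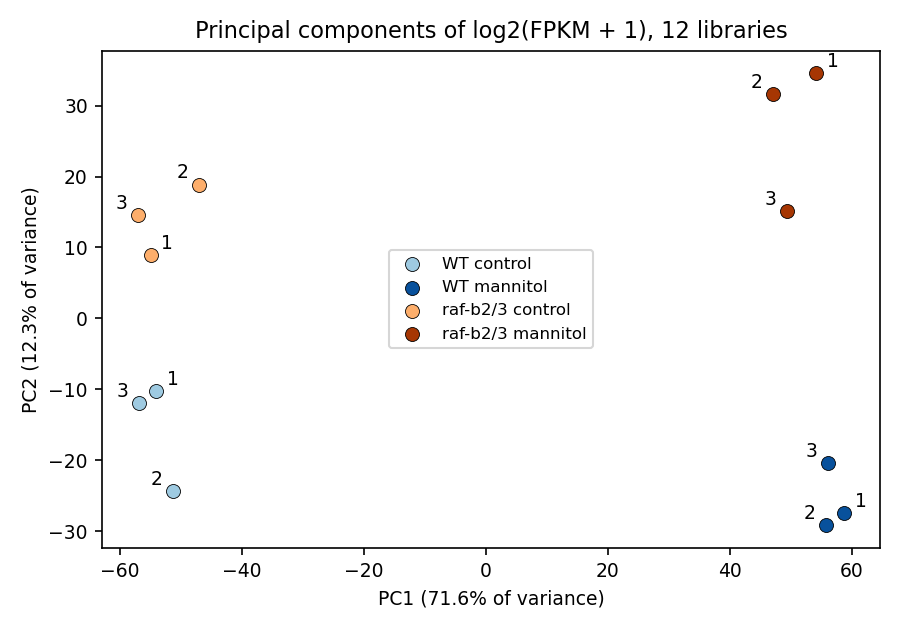
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis. Each point is 1 library, coloured by group and numbered by replicate. Control and mannitol libraries lie at opposite ends of the first axis, and raf-b2/3 mannitol 3 (15.15 on the second axis) lies below raf-b2/3 mannitol 1 and 2 (34.55 and 31.57).

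The response of WT seedlings to mannitol was examined first. Genes for LEA and dehydrin proteins, which accumulate in drying tissue, rose most among the named genes. RAB16D (LOC_Os11g26750) went from 0.783 ± 0.477 to 186 ± 39.3 FPKM, LEA3-1 (LOC_Os05g46480) from 24.2 ± 15.9 to 566 ± 102 and RAB16A (LOC_Os11g26790) from 23.7 ± 12.8 to 538 ± 85.2 (SD, n = 3). The silicon transporter gene LSI2 (LOC_Os03g01700) fell from 70.2 ± 44.7 to 2.1 ± 0.611 FPKM and the cytokinin response regulator gene RR10 (LOC_Os12g04500) from 47.2 ± 7.37 to 2.5 ± 0.523. In all, 3085 of 22371 genes passed the threshold, 1834 higher and 1251 lower, by limma-trend with Benjamini-Hochberg adjustment. The excess of higher genes depended on the scaling, with 1614 higher and 1506 lower under median-of-ratios scaling and 1541 and 1497 under quantile normalization. With a pseudocount of 0.1 it was 2532 and 1880, and by limma-voom on recovered reads 2555 and 1955. The log2 changes were 6.73 (SE 0.26, adjusted p 3.1e-09) for RAB16D, 4.76 (0.48, 3.4e-06) for LEA3-1, 4.60 for both RAB16A and RAB16C, 4.05 for the transcription factor NAC10 and 4.01 for the homeobox factor HOX24. They were -4.22 (SE 0.46, adjusted p 6.5e-06) for LSI2, -3.79 (0.15, 3.2e-09) for RR10, -3.06 for RR2, -2.85 for RR9, -2.81 for the iron transporter YSL15 and -2.62 for RR1. Reads of RAB16A to RAB16D, near-identical neighbours, could have been shared between copies.

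Of the lists tied to ABA and stress, 3 passed camera as higher in WT. All 8 LEA and dehydrin genes rose (median log2 4.26, camera adjusted p 3.6e-04), with adjusted p = 0.31 with an estimated correlation. All 9 clade A PP2C genes, whose products hold ABA signalling back and are themselves induced by ABA, rose (median 2.77, camera adjusted p 7.1e-05, and adjusted p = 0.31 with an estimated correlation). The call of PP2C53, 1 of the 9, ended under median-of-ratios scaling, quantile normalization, no filter, the replicate block, limma-voom and the fit without WT control 2 and raf-b2/3 mannitol 3. Among the 9, PP2C51 went from 0.458 ± 0.0594 to 8.93 ± 0.661 FPKM and PP2C09 from 8.81 ± 0.42 to 97.2 ± 2.45. Of 14 stress transcription factors 12 rose and 2 did not pass (median 1.42, camera adjusted p 3.5e-05, and adjusted p = 0.19 with an estimated correlation), with log2 changes of 2.89 for SNAC1 and 2.06 for BZIP46. Of 5 ABA receptor genes 3 fell and 2 did not pass, PYL6 by log2 -1.99, and the list did not pass camera (adjusted p 0.089) but passed fry (1.9e-05). Of 10 SnRK2 kinase genes 6 rose, among them SAPK6 by 1.87 and SAPK1 by 1.44, and 4 did not pass (camera adjusted p 0.11, fry adjusted p 9.8e-06). Of 7 ABA metabolism genes 5 rose, among them the synthesis gene NCED3 (1.40) and the breakdown gene ABA8OX2 (1.95), and 2 did not pass (camera adjusted p 0.093, and 0.049 under quantile normalization, with a fry adjusted p of 2.8e-05). Of 8 osmolyte synthesis genes 6 rose, P5CS2 of proline synthesis by 1.95, TPS1 fell by 1.16 on the log2 scale, and 1 did not pass (camera adjusted p 0.19, fry adjusted p 2.3e-06). In the small osmolyte turnover list, the proline dehydrogenase gene PRODH rose by 3.55 and BADH1 by 1.27, while BADH2 did not pass. Of the single stress markers SALT (2.75) and ASR5 (0.81) rose and ASR1 did not pass. Adjusted over the list alone, the counts of the lists fixed beforehand were the same, except that 3 single stress markers rose.

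Among the other lists some fell, some rose and some went both ways in WT. Of 8 type-A response regulators, which respond to cytokinin, 7 fell and RR3 did not pass (median -2.16, camera adjusted p 1.2e-05, and adjusted p = 0.19 with an estimated correlation). All 5 cell cycle genes fell (median -1.02, camera adjusted p 0.0021, and adjusted p = 0.31 with an estimated correlation), PCNA from 70.4 ± 6.11 to 23.5 ± 2.69 FPKM. Of 9 root markers 5 fell and 4 did not pass (median -1.01, camera adjusted p 0.013, and adjusted p = 0.61 with an estimated correlation), and without WT control 2 all 9 fell. Of 19 photosynthesis genes 8 fell, among them the Rubisco activase gene RCA (-1.37), and 11 did not pass (median -0.23, camera adjusted p 0.0064, and adjusted p = 0.65 with an estimated correlation). Under quantile normalization the photosynthesis median was -0.10 with adjusted p 0.49, and RBCS3, 1 of the 8, had a log2 change of 0.37. Of 12 expansin genes, whose products loosen cell walls, 4 rose and 4 fell, with a median of 0.23, a mean of 0.04 and a camera direction downward (adjusted p 0.66). Of 10 aquaporin genes 6 rose and 2 fell (camera adjusted p 0.49, fry adjusted p 0.003), 1 falling without WT control 1, WT mannitol 2 or WT mannitol 3, PIP1-2 going from 532 ± 22.6 to 902 ± 41.3 FPKM. Of 7 drought transcription factors 6 rose and DST fell (median 1.57, camera adjusted p 0.051), and of 8 JAZ repressors of jasmonate signalling 6 rose and 2 did not pass (median 0.81, camera adjusted p 0.089). The drought factor list passed without WT control 2 or 3 (adjusted p 0.038 and 0.047), raf-b2/3 control 2 or 3 (0.035 and 0.042) or raf-b2/3 mannitol 3 (0.049), without WT control 2 and raf-b2/3 mannitol 3 together (0.035), under median-of-ratios scaling (0.027), quantile normalization (0.023) and the replicate block (0.043), and by fry (1.3e-05). The JAZ list passed without WT control 1 (0.049) or raf-b2/3 control 2 (0.044), under quantile normalization (0.046) and by fry (0.0024). Of 12 heat shock genes 6 rose and 1 fell (camera adjusted p 0.51, fry adjusted p 0.025), 2 falling without WT control 2 or WT mannitol 2. Of 9 antioxidant enzymes 4 rose and 2 fell (camera adjusted p 0.85), 1 falling without WT mannitol 2, and of 5 alpha-amylases 2 rose (camera adjusted p 0.55, fry adjusted p 0.029). Of the 2 seed storage genes GLUA1 rose by 0.47 and GLUA2 did not pass. Of the 126 list genes past the adjusted p, 116 kept their call without each library, and leaving out WT control 1, 2 or 3 ended 3, 7 or 4 calls, WT mannitol 1, 2 or 3 ended 3, 4 or 7, and each raf-b2/3 control library ended that of PP2C53. The calls ended were those of CATC, HSP18.0, HSP82A, PIP2-4, PIP2-5, PP2C53, RCC3, SAPK8, TIFY10C and TPP1. Median-of-ratios scaling ended 6 of the 126 (HSP18.0, HSP82A, PIP2-1, PIP2-4, PP2C53 and SAPK8), which left 4 aquaporins higher and 2 lower and 4 heat shock genes higher and 2 lower, and quantile normalization ended 8 (APX8, CATC, HSP18.0, HSP82A, PIP2-4, PP2C53, RBCS3 and TIFY10C).

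The same treatment was then examined in raf-b2/3. PRODH (LOC_Os10g40360), which breaks down proline, rose most among the named genes, from 2.68 ± 0.638 to 79.1 ± 12 FPKM (SD, n = 3). RAB16D rose from 1.64 ± 0.504 to 29.0 ± 11.4 and RAB16A from 7.05 ± 1.47 to 58.7 ± 28.3. The silicon transporter genes LSI1 (LOC_Os02g51110) and LSI2 fell from 272 ± 19.2 to 15.9 ± 3.84 and from 110 ± 9.65 to 3.13 ± 0.367 FPKM. In all, 2779 genes passed the threshold, 1675 higher and 1104 lower, by limma-trend with Benjamini-Hochberg adjustment. Under median-of-ratios scaling 1502 were higher and 1299 lower, under quantile normalization 1477 and 1346, with a pseudocount of 0.1 the counts were 2372 and 1744, and by limma-voom on recovered reads 2393 and 1876. The log2 changes were 4.45 (SE 0.18, adjusted p 6.1e-09) for PRODH, 3.46 (0.26, 4.1e-07) for RAB16D, 3.33 for PP2C09, 2.99 for PP2C68, 2.95 for NAC10 and 2.80 for RAB16A. They were -4.75 (SE 0.46, adjusted p 3.2e-06) for LSI2, -4.04 (0.39, 3.5e-06) for LSI1, -3.50 for YSL15, -3.11 for RR10, -2.56 for RR9 and -2.47 for RR2.

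In raf-b2/3 all 8 LEA and dehydrin genes rose (median 1.82, camera adjusted p 0.012, and adjusted p = 0.48 with an estimated correlation), as did 8 of 9 clade A PP2C genes, PP2C53 not passing (median 1.94, camera adjusted p 3.6e-04, and adjusted p = 0.31 with an estimated correlation). Of 14 stress transcription factors 12 rose, and 13 adjusted over the list alone (median 1.10, camera adjusted p 5.4e-05, and adjusted p = 0.19 with an estimated correlation). All 8 JAZ repressors rose, TIFY11C by 2.34 and TIFY11E by 1.89 (median 1.59, camera adjusted p 0.0025, and adjusted p = 0.39 with an estimated correlation). Of 7 drought transcription factors 6 rose (median 1.97, camera adjusted p 0.021, and adjusted p = 0.31 with an estimated correlation). Of 8 type-A response regulators 7 fell (median -1.91, camera adjusted p 4.7e-05, and adjusted p = 0.19 with an estimated correlation). All 5 cell cycle genes fell (median -0.86, camera adjusted p 0.0026, and adjusted p = 0.31 with an estimated correlation), PCNA from 66.2 ± 5.25 to 21.2 ± 2.04 FPKM. Of 9 root markers 7 fell (median -1.72, camera adjusted p 0.0027, and adjusted p = 0.49 with an estimated correlation). Photosynthesis genes went both ways, 3 higher and 6 lower, with a median of 0.05, a mean of -0.15 and a camera direction downward (adjusted p 0.42), and the median was -0.03 under median-of-ratios scaling. Of 10 aquaporins 2 rose and 4 fell (median -0.14, camera adjusted p 0.35), and under median-of-ratios scaling 1 rose and 6 fell. The list passed fry (adjusted p 0.046), and 1 rose without raf-b2/3 control 1, raf-b2/3 control 3 or raf-b2/3 mannitol 3. Of 10 SnRK2 kinase genes 6 rose, of 7 ABA metabolism genes 4 rose, of 5 ABA receptors 2 fell, and of 8 osmolyte synthesis genes 5 rose and 1 fell, with camera adjusted p of 0.098, 0.2, 0.19 and 0.19 and fry adjusted p of 4.1e-05, 4.4e-04, 8.6e-05 and 2.3e-06. Of the osmolyte synthesis genes 4 rose and 2 fell without raf-b2/3 mannitol 3. The other counts of the lists fixed beforehand were the same adjusted over the list alone. Of the 123 list genes past the adjusted p, 108 kept their call without each library. Leaving out raf-b2/3 control 1, 2 or 3 ended 8, 5 or 7 calls, raf-b2/3 mannitol 1, 2 or 3 ended 6, 6 or 9, and each WT library ended that of HSP24.1. Among LEA genes the call of EMP1 (log2 0.73) ended, without raf-b2/3 control 1, raf-b2/3 control 2 or raf-b2/3 mannitol 3, without WT control 2 and raf-b2/3 mannitol 3 together, and under quantile normalization. Median-of-ratios scaling ended 6 of the 123 (HSFA2D, HSP24.1, HSP70-1, LHCA1, SAPK2 and TIP1-1), and quantile normalization 7 (APX8, EMP1, HSFA2D, HSP24.1, RBCS3, SAPK2 and SAPK7).

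Responses of the genotypes overlapped widely. Of the genes that rose, 1212 did so in both genotypes, where independent lists would share 137, and of those that fell, 816 did so in both, where independent lists would share 62. Across genes, which are not independent replicates, Pearson's r of the log2 responses was 0.89, and 0 genes were called in opposite directions. Of the 622 genes that passed as higher in WT alone, 98.9% had the same sign in raf-b2/3 and 196 passed the interaction test, and of the 463 that passed as higher in raf-b2/3 alone, 96.5% had the same sign in WT and 61 passed it. For falling genes the corresponding numbers were 435 in WT alone (97.7%, 46) and 288 in raf-b2/3 alone (96.5%, 15). Over the 1694 genes that rose in the mean of both genotypes, the median ratio of the raf-b2/3 to the WT response was 0.94, with medians of 1.48 in WT and 1.38 in raf-b2/3 and a smaller response in raf-b2/3 for 57.6%. Over the 1110 that fell it was 0.93, with medians of -1.32 and -1.26 and a smaller response for 60.9%. By limma's fry a shift in a common direction did not pass in either set (p 0.081 and 0.22), while its mixed form passed in both (p 4.0e-08 and 0.019). Among the rising genes the interaction passed for 206 with a smaller and 46 with a larger response in raf-b2/3, and among the falling ones for 27 and 8. Genes selected in WT alone gave ratios of 0.83 and 0.87, and genes selected in raf-b2/3 alone gave 1.08 and 1.03. For the rising set the shift passed with a filter at FPKM 5 (ratio 0.92, p 0.043), and for the falling set without raf-b2/3 mannitol 1 (ratio 0.91, p 0.035).

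The interaction asked which genes responded differently to mannitol in the 2 genotypes. LEA and dehydrin genes had a smaller rise in raf-b2/3: RAB16D reached 29.0 ± 11.4 FPKM under mannitol against 186 ± 39.3 in WT, LEA3-1 84.0 ± 26.1 against 566 ± 102 and RAB16C (LOC_Os11g26760) 8.54 ± 6.35 against 134 ± 24.9 (SD, n = 3). The galactinol synthase gene GOLS1 (LOC_Os03g20120), of raffinose sugar synthesis, went from 5.51 ± 0.83 to 11.7 ± 1.12 FPKM in WT and from 5.87 ± 0.855 to 4.92 ± 1.21 in raf-b2/3. The cell wall gene EXPB11 (LOC_Os02g44108) stood at 24.7 ± 2.23 and 23.1 ± 3.29 in WT and went from 25.2 ± 1.23 to 78.1 ± 20.7 in raf-b2/3. In all, 666 genes passed by limma-trend at adjusted p alone, 228 with a higher and 438 with a lower response in raf-b2/3, and 241 of them had a log2 interaction of at least 1 in size. Higher and lower give the sign of the interaction, so a weaker fall counts as higher and a deeper fall as lower. Among genes that fell in the mean of both genotypes there were 27 and 8 of these. The interaction was -3.27 (SE 0.36, adjusted p 8.7e-04) for RAB16D, -3.11 (0.68, 0.03) for LEA3-1, -2.89 (0.61, 0.025) for RAB16C, -1.19 (0.21, 0.011) for GOLS1, -0.98 for ABA8OX2 and -0.87 for PP2C08. It was 1.66 (SE 0.21, adjusted p 0.0017) for EXPB11, 1.15 (0.25, 0.029) for the heat shock factor HSFA2D, 0.75 for EXPA4, 0.63 for EXPB3 and 0.39 for the JAZ repressor TIFY10B. The number of genes was 305 without WT mannitol 1 (86 higher and 219 lower), 364 without WT mannitol 2 (102 and 262), 443 without raf-b2/3 control 1 (123 and 320), 402 without raf-b2/3 control 3 (120 and 282), 380 without raf-b2/3 mannitol 2 (108 and 272) and 781 without raf-b2/3 mannitol 3 (320 and 461), 531 without WT control 1 (143 and 388), 841 without WT control 2 and raf-b2/3 mannitol 3 together (387 and 454), 1200 with array weights (500 and 700), 452 with a pseudocount of 0.1 (149 and 303) and 359 by limma-voom on recovered reads (122 and 237). Under median-of-ratios scaling 266 were higher and 382 lower, and under quantile normalization 287 and 387. Lower responses were the more numerous in each of these settings, by the smallest margin in the fit without the pair of libraries.

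**Figure D2:**
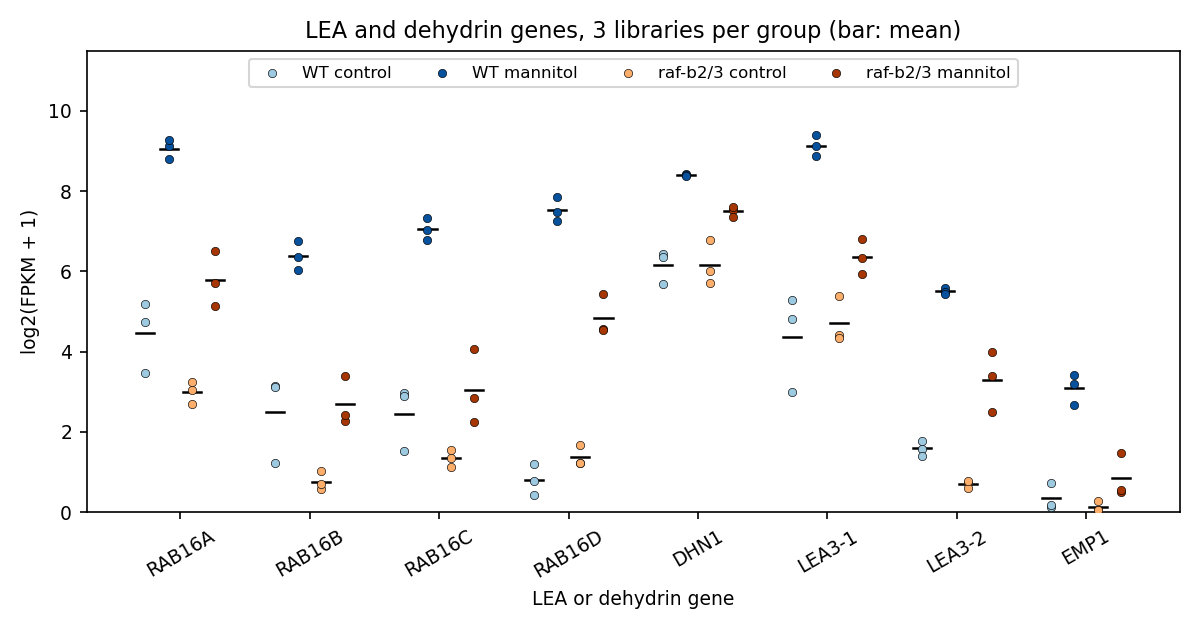
Log2(FPKM + 1) of the 8 LEA and dehydrin genes in the 12 libraries, in 4 groups per gene. Each point is 1 library and each bar the mean of 3. The mannitol libraries of raf-b2/3 lie below those of WT for RAB16A, for example 58.7 ± 28.3 against 538 ± 85.2 FPKM.

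Among the lists, the LEA and dehydrin genes had the largest median interaction. It was -1.99 (camera adjusted p 2.7e-07), with adjusted p = 0.22 with an estimated correlation. Of the 8 genes, RAB16C, RAB16D, LEA3-1 and EMP1 passed over all genes and 8 passed adjusted over the list alone. Over all genes 2 passed without WT mannitol 1, WT mannitol 2, raf-b2/3 control 1 or raf-b2/3 mannitol 2. In raf-b2/3 mannitol 3, the library nearest to WT mannitol, RAB16A stood at 89.7 FPKM, against 34.4 and 51.8 in raf-b2/3 mannitol 1 and 2, and without that library the list median was -2.32. For clade A PP2C genes the median was -0.68 (camera adjusted p 8.6e-05, and adjusted p = 0.31 with an estimated correlation), with PP2C06, PP2C08 and PP2C51 of 9 passing, and 5 adjusted over the list alone. Over all genes 1 passed without WT control 2 or 3, WT mannitol 1, 2 or 3, raf-b2/3 control 2 or 3 or raf-b2/3 mannitol 2, and 5 passed without raf-b2/3 mannitol 3. For aquaporins it was -0.42 (camera adjusted p 7.1e-05, and adjusted p = 0.22 with an estimated correlation), with PIP1-1 and PIP1-2 of 10 passing (0 without WT mannitol 1), and 5 adjusted over the list alone. PIP1-2 stood at 497 ± 19.3 and 558 ± 40.6 FPKM in raf-b2/3 control and mannitol. For stress transcription factors it was -0.30 (camera adjusted p 6.1e-04, and adjusted p = 0.19 with an estimated correlation), with BZIP46 (-0.75) of 14 passing, and 7 adjusted over the list alone, while over all genes 2 passed without WT control 3 or raf-b2/3 mannitol 1 and 3 without raf-b2/3 mannitol 3. Of 10 SnRK2 kinase genes SAPK1 (-0.67) and SAPK3 (-0.83) passed, of 8 osmolyte synthesis genes P5CS1 (-0.60) and GOLS1, and of 7 ABA metabolism genes ABA8OX2, with camera adjusted p of 0.25, 0.49 and 0.2, the last list passing without WT control 2 and raf-b2/3 mannitol 3 together (0.041). Adjusted over the list alone these 3 lists had 2 lower, 4 higher and 2 lower, and 1 lower, and the ABA receptor, Raf-like kinase and single stress marker lists had 0 before and after.

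Of the lists past camera, 4 had a median above 0. The medians were 0.50 for JAZ repressors (1 of 8 genes passing, camera adjusted p 3.6e-04, and adjusted p = 0.31 with an estimated correlation), 0.27 for type-A response regulators (0 of 8, camera adjusted p 0.0021, and adjusted p = 0.31 with an estimated correlation) and 0.22 for photosynthesis (0 of 19, camera adjusted p 7.1e-05, and adjusted p = 0.49 with an estimated correlation). For expansins the median was 0.12, with 3 of 12 passing (camera adjusted p 0.038, and adjusted p = 0.49 with an estimated correlation), and 1 without WT control 3, WT mannitol 1 or raf-b2/3 control 1, 2 or 3. Without raf-b2/3 control 3 the call of EXPA4 ended and that of EXPB3 lay at the threshold. By fry the JAZ, photosynthesis and expansin lists did not pass (adjusted p 0.062, 0.17 and 0.12). The expansin result was lost without WT control 1, 2 or 3 (adjusted p 0.089, 0.08 and 0.099), WT mannitol 1 (0.061), raf-b2/3 control 1 (0.065), raf-b2/3 mannitol 2 (0.073) and raf-b2/3 mannitol 3 (0.059), without WT control 2 and raf-b2/3 mannitol 3 together (0.12), and under median-of-ratios scaling (0.056). The median for root markers was -0.53 (camera adjusted p 0.2), and without WT control 3 it was -0.91 with adjusted p 0.014. For drought transcription factors the median was -0.05 and the mean -0.25 with a camera direction upward (adjusted p 0.78). For cell cycle genes the median was -0.05 and the mean 0.03 (adjusted p 0.77).

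Of the 20 list genes past the interaction test, BZIP46, EMP1, EXPB11, GOLS1, PP2C51, RAB16D and SAPK1 kept their call without each library. ABA8OX2 lay at the threshold without WT mannitol 2, where its adjusted p rounded to 0.05 and the count of passing ABA metabolism genes was 0. The other 12 lost their call without at least 1 library, with highest adjusted p from 0.051 for PIP1-1 to 0.12 for TIFY10B, and 0.08 for LEA3-1 and 0.07 for RAB16C. Leaving out WT control 1, 2 or 3 ended 3, 5 or 6 of these calls, WT mannitol 1, 2 or 3 ended 12, 7 or 4, raf-b2/3 control 1, 2 or 3 ended 8, 7 or 7, and raf-b2/3 mannitol 1, 2 or 3 ended 3, 8 or 1. These numbers leave out calls at the threshold, those of ABA8OX2 without WT mannitol 2, TIFY10B without WT mannitol 3 and EXPB3 without raf-b2/3 control 3. Limma-voom on recovered reads ended 8 calls (ABA8OX2, EMP1, PP2C06, PP2C08, PP2C51, RAB16C, RAB16D and TIFY10B). A pseudocount of 0.1 ended 6 (EMP1, PP2C06, PP2C08, PP2C51, RAB16C and TIFY10B). The replicate block ended 5 (EXPA4, PP2C06, PP2C08, RAB16C and TIFY10B), no filter 4 (EXPA4, PP2C06, PP2C08 and TIFY10B), rescaling each library to the same total 3 (PP2C06, PP2C08 and TIFY10B), leaving out both WT control 2 and raf-b2/3 mannitol 3 ended 2 (EXPA4 and PP2C06), and median-of-ratios scaling and quantile normalization ended that of PP2C06. BZIP46, EXPB11, GOLS1 and SAPK1 also stayed past the adjusted p under each other filter, scaling, weighting and test run, the added fold threshold aside.

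**Figure D3:**
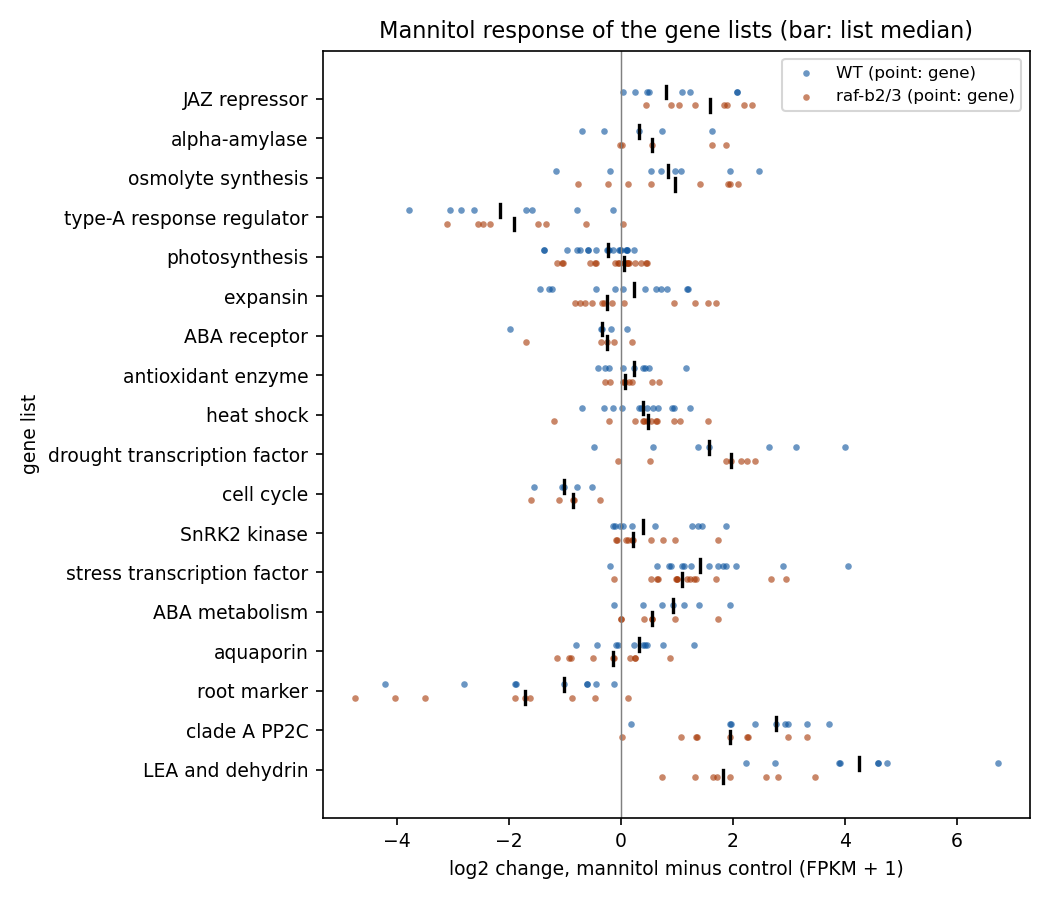
Log2 change under mannitol of the genes of 18 lists in WT and raf-b2/3, sorted by the median interaction. Each point is 1 gene and each bar the list median. For LEA and dehydrin genes the medians are 4.26 in WT and 1.82 in raf-b2/3, and for JAZ repressors 0.81 and 1.59.

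Without mannitol, the genotypes differed in few genes. Among the named genes, DSM1 alone passed the fold threshold, and it was lower in raf-b2/3 (9.1 ± 0.375 against 21.7 ± 1.56 FPKM). The ABA receptor gene PYL6 was higher, at 45.6 ± 4.74 against 25.1 ± 2.69 FPKM (SD, n = 3; log2 0.84, limma adjusted p 0.0055). In all, 133 genes passed the threshold, 90 higher and 43 lower in raf-b2/3, by limma-trend with Benjamini-Hochberg adjustment. By locus number, the highest log2 differences were 5.85 for LOC_Os01g35330 and 5.53 for LOC_Os03g02470, and the lowest were -4.25 for LOC_Os01g74640 and -8.05 for LOC_Os01g74650. The last belongs to a group of 5 neighbouring loci, LOC_Os01g74610 to LOC_Os01g74670, the highest numbered on chromosome 1 in the table, which was singled out after its values were seen. LOC_Os01g74650 stood at 334 ± 13.4 FPKM in WT control and 0.294 ± 0.353 in raf-b2/3 control. Under mannitol it stood at 194 ± 1 in WT and at 0.0592, 0.103 and 29 in raf-b2/3 mannitol 1, 2 and 3. LOC_Os01g74660 and LOC_Os01g74670 had 0 reads in each raf-b2/3 control library, for which the upper 95% limits reach 0.88% and 5.57% of the WT level, and had 54 and 9 reads in raf-b2/3 mannitol 3. With only the 2 groups compared in the fit, 87 genes passed (54 higher and 33 lower), and with a filter at FPKM 5, 77 did (52 and 25).

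**Figure D4:**
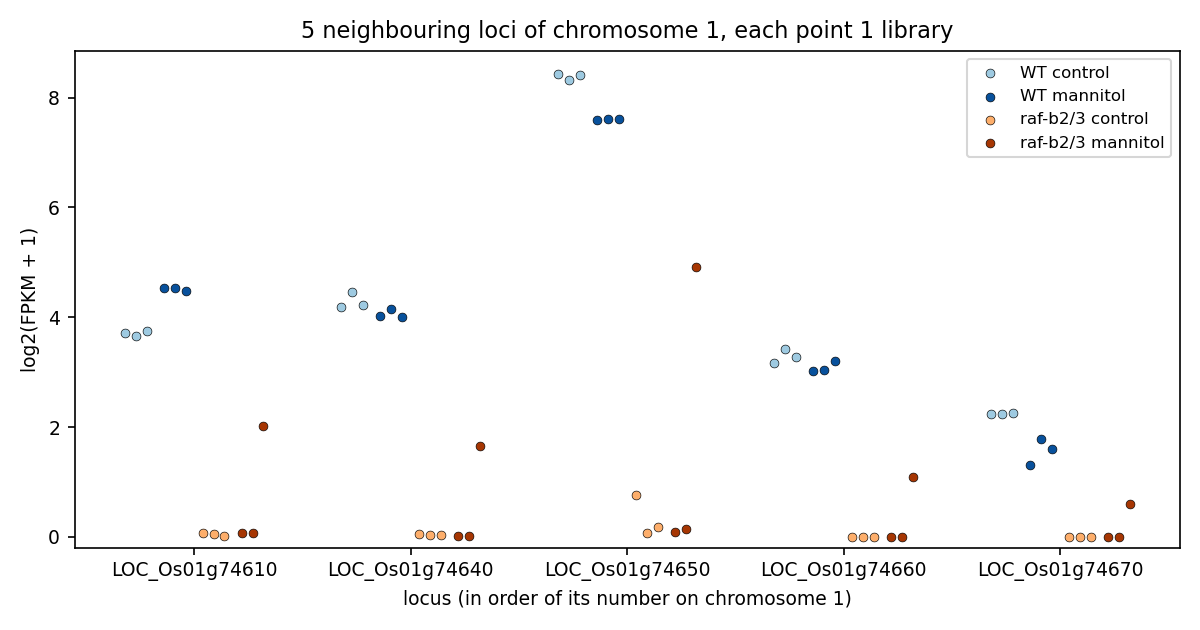
Log2(FPKM + 1) of 5 neighbouring loci of chromosome 1 in the 12 libraries, with 1 point per library. All 5 loci are near 0 in raf-b2/3 control and in raf-b2/3 mannitol 1 and 2, and above 0 in raf-b2/3 mannitol 3, where LOC_Os01g74650 stands at 29 FPKM against 194 ± 1 in WT mannitol.

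Among the lists, 3 tied to ABA were lower in raf-b2/3 without mannitol by camera. Of 9 clade A PP2C genes PP2C08 (log2 -0.60, adjusted p 0.049) and PP2C09 (-0.60, 0.026) were lower and 7 did not pass (median -0.16, camera adjusted p 0.0061, and adjusted p = 0.47 with an estimated correlation). Of 8 LEA and dehydrin genes 0 passed over all genes and 4 were lower adjusted over the list alone, and over all genes 2 were lower without WT control 3 and 1 without raf-b2/3 mannitol 1 or 3 (median -0.55, camera adjusted p 0.03, and adjusted p = 0.49 with an estimated correlation). Of 7 ABA metabolism genes 0 passed and 2 were lower adjusted over the list alone (median -0.36, camera adjusted p 0.022, and adjusted p = 0.31 with an estimated correlation). By fry the clade A PP2C and LEA lists did not pass (adjusted p 0.16 and 0.27), while the ABA receptor list did (0.019). All 3 list results were lost without WT control 1 (adjusted p 0.098, 0.16 and 0.085), and that of the LEA genes also without WT control 2 (0.084), raf-b2/3 control 1 (0.055) or raf-b2/3 control 3 (0.052), without WT control 2 and raf-b2/3 mannitol 3 together (0.055), under median-of-ratios scaling or quantile normalization (0.076 in both) and with the replicate block (0.057). The calls of both PP2C genes ended without WT control 1 or 3 and without raf-b2/3 control 2 or 3, and limma-voom ended both. That of PP2C09 also ended without WT control 2. That of PP2C08 also ended without WT mannitol 1, 2 or 3, raf-b2/3 control 1 or raf-b2/3 mannitol 2, and with a filter at FPKM 5, no filter and the replicate block. Adjusted over the list alone, 1 aquaporin and 1 osmolyte synthesis gene were lower and 1 SnRK2 kinase and 2 stress transcription factors were higher, none of which passed over all genes. For root markers the median was 0.45 (0 of 9 passing, camera adjusted p 0.075), and it passed without WT control 1 (0.75, adjusted p 0.017), without WT control 3 (0.83, adjusted p 7.4e-04) and without raf-b2/3 control 2 (0.65, adjusted p 0.027), and under median-of-ratios scaling (0.44, adjusted p 0.04) and quantile normalization (0.40, adjusted p 0.036). For photosynthesis it was -0.08 (0 of 19, camera adjusted p 0.19), with 0.01 under quantile normalization, and it passed without raf-b2/3 control 3 (-0.13, adjusted p 0.022).

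Under mannitol, the named genes furthest below WT in raf-b2/3 were LEA genes. RAB16B (LOC_Os11g26780) stood at 5.92 ± 3.18 FPKM in raf-b2/3 against 84.3 ± 21.5 in WT, and LEA3-2 (LOC_Os03g20680) at 9.66 ± 5.11 against 44.6 ± 2.46 (SD, n = 3). PRODH and the ABA receptor gene PYL6 were higher in raf-b2/3, at 79.1 ± 12 against 36.9 ± 3.25 and at 13.5 ± 1.76 against 5.6 ± 1.03. In all, 509 genes passed the threshold, 257 higher and 252 lower in raf-b2/3, by limma-trend with Benjamini-Hochberg adjustment. The lowest log2 differences were -4.01 for RAB16C (SE 0.43, adjusted p 9.8e-05), -3.68 for RAB16B (0.45, 2.2e-04), -3.27 for RAB16A, -2.77 for LEA3-1, -2.68 for RAB16D and -2.22 for LEA3-2. The highest were 1.69 for EXPB11 (SE 0.15, adjusted p 2.4e-05), 1.14 for PYL6 (0.13, 1.3e-04), 1.07 for PRODH and for the transcription factor BHLH148, 1.06 for HSFA2D and 1.02 for TPP1 of trehalose synthesis. By locus number, LOC_Os01g35330 (6.51) and LOC_Os03g02470 (4.68) were highest and LOC_Os01g74650 (-5.90) and LOC_Os11g26570 (-4.89) lowest. With a pseudocount of 0.1, 805 genes passed (464 higher and 341 lower), and 891 by limma-voom on recovered reads (509 and 382), while 363 did with a filter at FPKM 5 (162 of them higher).

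All 8 LEA and dehydrin genes were lower in raf-b2/3 under mannitol (median -2.73, camera adjusted p 1.7e-08, and adjusted p = 0.19 with an estimated correlation), with DHN1 at 181 ± 15.2 against 337 ± 8.02 FPKM. Root markers, measured beside them as a sign of tissue make-up, had a median of 0.03, with -0.01 under quantile normalization, and 0 of 9 passed (camera adjusted p 0.95), while without WT control 2 there were 1 higher and 2 lower. Of 9 clade A PP2C genes 6 were lower (median -0.62, camera adjusted p 2.4e-06, and adjusted p = 0.27 with an estimated correlation), PP2C51 at 2.01 ± 0.446 against 8.93 ± 0.661 FPKM. Of 10 aquaporins 6 were lower, and 8 adjusted over the list alone (median -0.52, camera adjusted p 1.2e-05, and adjusted p = 0.19 with an estimated correlation). Of 14 stress transcription factors 6 were lower (median -0.27, camera adjusted p 0.025, and adjusted p = 0.31 with an estimated correlation), BZIP46 at 22.4 ± 1.82 against 41.5 ± 1.9 FPKM, and adjusted over the list alone 1 was higher and 6 lower. Of 7 ABA metabolism genes 3 were lower, NCED4 and the breakdown genes ABA8OX2 and ABA8OX3 (median -0.22, camera adjusted p 0.012, and adjusted p = 0.27 with an estimated correlation). Of 10 SnRK2 kinase genes 1 was higher and 3 lower, and of 8 osmolyte synthesis genes 4 were higher and 3 lower, with camera adjusted p of 0.49 and 0.99. The trehalose genes TPP1, TPP2, TPP7 and TPS1 were the higher ones, and P5CS1, GOLS1 and GOLS2 the lower ones, and 2 were higher without WT mannitol 1, WT mannitol 2 or raf-b2/3 mannitol 1. Of 5 ABA receptors 2 were higher, and 1 without WT mannitol 1 (camera adjusted p 0.093, fry adjusted p 7.8e-04), and the list passed camera without WT mannitol 3 (0.049).

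By camera, 4 lists were higher in raf-b2/3 under mannitol. Of 8 JAZ repressors 5 were higher (median 0.66, camera adjusted p 8.6e-05, and adjusted p = 0.31 with an estimated correlation). Of 8 type-A response regulators 5 were higher (median 0.39, camera adjusted p 5.8e-04, and adjusted p = 0.27 with an estimated correlation), RR10 at 5.08 ± 0.869 against 2.5 ± 0.523 FPKM, but 2 were higher without WT mannitol 1 or raf-b2/3 mannitol 2 and 3 without raf-b2/3 mannitol 3. Of 12 expansins 4 were higher (median 0.23, camera adjusted p 0.012, and adjusted p = 0.47 with an estimated correlation). Of 19 photosynthesis genes 4 were higher (median 0.18, camera adjusted p 0.0026, and adjusted p = 0.64 with an estimated correlation), a result lost without raf-b2/3 mannitol 3 (median 0.09, adjusted p 0.14), and also without WT control 2 and that library together (adjusted p 0.18) and by fry (adjusted p 0.14). Of these genes 1 was higher without WT mannitol 1, WT mannitol 2 or raf-b2/3 mannitol 2, and 2 without raf-b2/3 mannitol 3. Of the 73 list genes past the adjusted p, 55 kept their call without each library. This tally counts calls at the threshold as kept, among them 1 ABA receptor call without WT mannitol 1. Leaving out WT mannitol 1, 2 or 3 ended 16, 13 or 9 calls and raf-b2/3 mannitol 1, 2 or 3 ended 9, 15 or 9, that of DHN1 with each of these 6 except raf-b2/3 mannitol 3. The control libraries whose omission ended calls were WT control 1 (2) and 3 (3) and raf-b2/3 control 1 (3), 2 (1) and 3 (4). The calls of NCED4, TPP2 and TPP7 were among those that ended. The replicate block ended 5 of the 73 (EDR1, HSP70-2, LHCB4, RR3 and TPP7), and the fit without WT control 2 and raf-b2/3 mannitol 3 ended 7 (HSP70-2, LHCB4, PIP2-5, PSAF, RR2, RR3 and RR4).

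The authors' deposited table sorts loci into those changed by mannitol in both genotypes and those changed in 1 genotype. The authors' deposited table lists 440 loci as higher in WT alone, 491 as higher in raf-b2/3 alone and 680 as higher in both, and 386, 279 and 478 as lower in the same order. Of the loci that were tested here, the interaction passed for 94 of 252 (37.3%) that the authors' deposited table lists as higher in WT alone, 27 of 210 (12.9%) listed as higher in raf-b2/3 alone and 100 of 549 (18.2%) listed as higher in both. For loci that the authors' deposited table lists as lower it passed for 16 of 187 (8.6%), 10 of 119 (8.4%) and 6 of 324 (1.9%). Across genes, the log2 changes of the authors' deposited table and those fitted here had a Pearson's r of 0.919 in WT and 0.921 in raf-b2/3.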

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

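Of the tests in this part, those on tissue markers and on the LEA genes outside the RAB16 group were chosen only after the result was seen. The results below stand out because the response to mannitol differed between genotypes by a test of the difference itself, for 666 genes in all.

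The LEA and dehydrin genes had a smaller response in raf-b2/3 (median interaction -1.99). Library scaling is argued against, since under 3 other scalings the median moved by at most 0.04, and a single library does not carry it, since the median nearest to 0 with 1 library left out was -1.63 (without WT control 3). Tissue markers gave no sign of a genotype difference under mannitol as large as that of the LEA genes (-2.73), with medians of 0.03 for root markers and 0.18 for photosynthesis genes. Their median interactions were -0.53 (-0.91 without WT control 3) and 0.22. Root markers themselves fell under mannitol, by medians of -1.01 in WT and -1.72 in raf-b2/3. They therefore do not measure tissue share alone, and the markers do not settle whether tissue make-up differed. Reads shared between the RAB16 copies are argued against for the list, since its 4 members outside the RAB16 group had a median interaction of -1.68 (-3.11 to -0.91), though how reads were divided among the copies is not known. Tissue make-up stays open. Also open are the genotype itself, which may act on these genes, and any difference in how the seedlings of each group were grown, neither of which was tested. The individual interactions past the threshold were -2.89 for RAB16C, -3.27 for RAB16D, -3.11 for LEA3-1 and -2.02 for EMP1. Limma-voom ended the calls of RAB16C, RAB16D and EMP1, and a pseudocount of 0.1 those of RAB16C and EMP1. LEA3-1 lost its call when any of 6 libraries was left out. EMP1 was low in raf-b2/3, at 0.0308 to 0.221 FPKM in control and 0.424 to 1.8 under mannitol. The list median was -2.03 with a pseudocount of 0.1 and -1.80 by limma-voom.

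Other lists had median interactions of -0.42 (aquaporins), -0.68 (clade A PP2C), -0.30 (stress transcription factors), 0.22 (photosynthesis), 0.50 (JAZ repressors), 0.27 (type-A response regulators) and 0.12 (expansins). These lists and the LEA list passed camera with the preset correlation only. With an estimated correlation the adjusted p ran from 0.19 for stress transcription factors to 0.49 for photosynthesis and expansins. By fry, photosynthesis (adjusted p 0.17), JAZ repressors (0.062) and expansins (0.12) did not pass. Other named genes with a negative interaction were PP2C06 (-0.45), PP2C08 (-0.87) and PP2C51 (-1.42), the kinases SAPK1 (-0.67) and SAPK3 (-0.83), ABA8OX2 (-0.98), BZIP46 (-0.75), P5CS1 (-0.60), GOLS1 (-1.19), PIP1-1 (-0.58) and PIP1-2 (-0.59). A positive interaction, which can also be a weaker fall, was found for HSFA2D (1.15), TIFY10B (0.39), EXPA4 (0.75), EXPB3 (0.63) and EXPB11 (1.66). With a pseudocount of 0.1 the calls of PP2C06, PP2C08, PP2C51 and TIFY10B ended.

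Exchanging genotype labels within each treatment gave as many genes as the real 666 in 3 of 100 splits, the real one included, and the highest other split gave 1455 genes. This share does not decide on chance for the interaction. Most splits mix the genotypes, so that genotype differences enter the spread within groups and can lower their counts. The splits with more genes (1455 and 1065) exchanged 2 control libraries, or all 3 mannitol libraries with 1 control library, so both kept the mannitol libraries of each genotype together and the genotype difference under mannitol enters their counts. Why they gave more genes was not tested. For the response size, 23 of 100 splits gave a median difference as large as 0.10 for rising genes (highest other 0.18) and 32 of 100 as large as 0.09 for falling genes (highest other 0.21), so chance was not excluded. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. There 1 split, the real one, gave as many genes in each, with 3085 in the WT response (highest other 0), 2779 in the raf-b2/3 response (0), 133 for genotype without mannitol (7) and 509 under mannitol (0).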

How the results depend on the processing

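The limma-voom test and the fit without WT control 2 and raf-b2/3 mannitol 3 were chosen after the data were seen. Of 885 results for single genes, 346 of them past the adjusted p, 2 changed sign while past it, those of RBCS3, with a log2 change of 0.37 in both responses under quantile normalization (the cause was not tested). Of the 90 list results, 35 past the threshold, an estimated correlation ended 35, fry 6, a pseudocount of 0.1 ended 0, median-of-ratios scaling 2, quantile normalization 2, the replicate block 1 and the fit without the 2 libraries 3, while fry brought 18 others past it, median-of-ratios scaling 2, quantile normalization 4, the replicate block 1 and the fit without the 2 libraries 2. Fry's adjusted p in the 6 was 0.12 for expansins, 0.062 for JAZ repressors and 0.17 for photosynthesis in the interaction, 0.16 for clade A PP2C and 0.27 for LEA genes without mannitol, and 0.14 for photosynthesis under mannitol.

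At adjusted p alone, 14151 genes passed in the WT response, 13923 in the raf-b2/3 response, 404 for genotype without mannitol and 3544 under mannitol, and with the fold threshold added 241 passed the interaction, all by construction. Limma-voom gave 4269 in the raf-b2/3 response, 359 in the interaction and 891 under mannitol, and array weights 1200 in the interaction. Without mannitol, 77 passed at FPKM 5 (fewer genes tested) and 87 with the 2 groups compared alone (fewer samples). Under mannitol 805 passed with a pseudocount of 0.1. Apart from those made by construction, the causes of these moves were not tested. With 1 library left out, the counts were 3020 to 3196, 2662 to 2955, 305 to 781 (lowest without WT mannitol 1, highest without raf-b2/3 mannitol 3), 96 to 141 and 418 to 647, for the WT response, the raf-b2/3 response, the interaction and genotype without and under mannitol. The response size was 0.92 to 0.99 for rising and 0.91 to 0.97 for falling genes. At FPKM 5 it was 0.92 for rising genes with fry p 0.043. It was 0.83 and 0.87 (p 0.0017 and 0.029) for genes called in WT alone, and reversed to 1.08 and 1.03 (p 0.42 and 0.63) for genes called in raf-b2/3 alone, since selection in 1 genotype favours that genotype.

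Without WT control 2 and raf-b2/3 mannitol 3 the counts were 3102, 2896, 841, 116 and 666, in the same order. Replicate numbers gave no sign of pairing: same-numbered libraries correlated in their deviations from the group mean with r of -0.311 to 0.265 over 18 pairs, and 4 of 12 libraries correlated best with their own number. With the replicate block, the counts were 3085, 2778, 556, 125 and 508. In the simulation, which did not vary depth, a log2 change of 0.5 was recovered for 42.0% of genes in the interaction. Differences of that size or less could therefore often be missed there.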

Other observations

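The tests on raf-b2/3 mannitol 3 and on the loci without reads in WT were chosen only after the results had been seen.

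Under mannitol, antioxidant enzymes went both ways between genotypes. The catalase gene CATC was higher in raf-b2/3 (log2 0.57, limma adjusted p 0.009), while the superoxide dismutase genes SODCC2 (-0.66, 0.013) and SODA (-0.52, 0.03) were lower, and 6 of 9 did not pass (camera adjusted p 0.83). The call of SODCC2 ended without WT mannitol 3 or raf-b2/3 mannitol 2, and that of SODA without WT mannitol 1, 2 or 3 or raf-b2/3 mannitol 1 or 2. ASR5, a stress and ripening gene, rose in WT (0.81, adjusted p 1.5e-04), did not pass in raf-b2/3 (0.31, 0.055) and was lower in raf-b2/3 under mannitol (-0.81, 0.0013), although its interaction did not pass (-0.51, 0.18). In raf-b2/3, 8 of 12 heat shock genes rose under mannitol and 2 fell (5 and 2 under median-of-ratios scaling and without raf-b2/3 control 1 or raf-b2/3 mannitol 1, 5 and 1 without raf-b2/3 control 3 or raf-b2/3 mannitol 2, and 8 and 1 without raf-b2/3 control 2 or raf-b2/3 mannitol 3), 2 of 9 antioxidant enzymes rose and 1 fell, 2 of 5 alpha-amylases rose, and 4 of 12 expansins rose and 4 fell, with camera adjusted p of 0.23, 0.81, 0.44 and 0.81, and heat shock genes and alpha-amylases passed fry (adjusted p 0.0077 and 0.017). For the expansins the median was -0.24, the mean 0.17 and the camera direction downward.

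In raf-b2/3 mannitol 3, the 5 chromosome 1 loci that the other raf-b2/3 libraries nearly lacked stood at a pooled 14.4% of the WT mannitol level (13.8 to 25.7% per locus, 9 to 2488 reads), while the highest pooled share in the other 5 libraries was 0.22%, which argues against index exchange at a like rate in all libraries. All 5 shares lay around 1 common value, so a candidate explanation is that some seedlings of this library kept a chromosome 1 segment that the others lack. Mixed-in WT RNA is a rival explanation, since genes called between genotypes without mannitol lay a median of 15.8% toward WT in this library (interval 12.5 to 23.9, 67 genes), but raf-b2/3 control 1 also gave 11% (5.6 to 14.7). The other libraries gave -0.5% (raf-b2/3 control 2), 4.7% (control 3), -4.5% (mannitol 1) and -9.7% (mannitol 2), each measured from the other 2 libraries of its group, so raf-b2/3 mannitol 3 itself enters the values of mannitol 1 and 2. The intervals of these positions come from resampling genes, which are not independent replicates, and do not cover the spread between libraries. The genes were called with the control libraries, so the control positions are not independent of that choice. A further locus absent from the raf-b2/3 controls (under 5% of WT), LOC_Os06g11240, had 0 reads, 0.0% of the 113 that mixing predicts (upper limit 3.3%), but this limit was settled on after limits of 10% and 20% had been seen, where 3 and 11 other loci gave 25.6% and 92.6% of the predicted reads, and it rests on 1 locus. The same loci gave 19.3% and 37.9% in raf-b2/3 mannitol 1 and 8.52% and 47.2% in raf-b2/3 mannitol 2, so part of that level is not specific to this library. The rival explanations cannot be told apart with these values.

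Reads at loci silent in WT were more frequent than the reverse: 153 loci had no read in the 6 WT libraries and reads in all 6 raf-b2/3 libraries, against 53 the other way. Loci without reads numbered 1726 to 1819 per library in WT control, 1587 to 1677 in WT mannitol, 1453 to 1570 in raf-b2/3 control and 1179 to 1235 in raf-b2/3 mannitol. Greater depth is argued against, since the median relative depth of raf-b2/3 was -1.6% relative to WT. An even background such as genomic DNA stays open. For 13.1% of the 153 loci, the total reads lay within the counting interval of 1 density per length shared by all of them. How reads lay along each locus was not examined. But the loci were picked for having reads in all 6 raf-b2/3 libraries, their median of 27 reads over 6 libraries is low, and their totals per library (1975 to 2844) lay within 1.5 times of each other. Sequence differences between the line and WT stay open and were not tested.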
